A study of Mus musculus with 12 samples.

How the data were processed

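RNA was measured in LSK and GMP cells of WT and Tet2-/-Flt3ITD mice, with 3 libraries in each of 4 groups. Per the labels' protocols, marrow was flushed from femur and tibia, red cells were lysed, cells that bear mature lineage markers were depleted, and the populations were sorted by flow cytometry. The lineage antibodies named there were against CD3, Gr-1, Mac-1, NK1.1, B220 and Ter119. RNA was extracted with Trizol, ribosomal RNA was depleted from 100 ng with RiboMinus, and libraries were made with an Ion Total RNA-seq kit, per the labels' protocols. Depletion of ribosomal RNA without selection of poly(A) leaves small noncoding and unspliced RNA in the libraries, so these can take a share of the counts. Per the submitters' processing notes, the tools were BWA 0.5.9, TopHat, TopHat2, cutadapt, Picard and HTSeq with the mm9 build, and their order and settings are not given in the sources used here. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as histone, ribosomal protein and T cell receptor genes are uncertain. The authors deposited a table of raw gene counts, with no normalization, for all libraries together.

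The table had 21497 entries that pair an Ensembl identifier with a symbol, 366 of them at 0 in every library. Symbols were written in the current mouse form for the 19939 identifiers found in GENCODE vM21 names, and as deposited for the other 1558, and since that annotation is of another build no coordinates were used. The smallest depth was 13316474 counts (WT LSK replicate 3) and the greatest 23536258 counts (T2F3 GMP replicate 2). A count of 0 allows up to 3 counts, which was between 0.1115 and 0.228 CPM in these libraries, and this floor and the 95% counting intervals cover counting error only. Folds against a group with no counts were computed against that floor and are lower bounds, and genes with 1 to 3 counts in a group are given as a ratio with its interval. No library pair within a group agreed within sampling noise (chi-square per degree of freedom of 79.6 to 419 over genes with at least 20 counts summed over the pair).

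Genes were kept by filterByExpr of edgeR by group (minimum count 10), which left 16042. Counts were scaled by TMM and tested by the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 mean per group over all 12 libraries, so that the groups share an estimate of the spread (8 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each of 5 comparisons, T2F3 with WT in LSK and in GMP, the difference between these 2 effects, and GMP with LSK in WT and in T2F3, and an adjusted p under 0.05 was called. The 28 gene lists, with 837 different members, of which 33 were in more than 1 list, were tested against other genes by camera with a preset correlation of 0.01 and again with an estimated correlation, and a list needed 5 tested members. In LSK 20 lists were called with the preset and 2 with the estimated correlation, in GMP 14 and 2, for the difference 16 and 0, and between GMP and LSK 24 and 6 in WT and 17 and 7 in T2F3. Those lists, the tests and the rule for named genes were chosen before the data were examined, except that the name patterns of the histone and ribosomal protein lists were refined after gene names, not values, were seen. The rule took Tet2, Flt3, Kit, Ly6a, Cd34, Fcgr3, Gata1, Gata2 and Gata3 everywhere, the 10 genes with the largest rise and fall per genotype comparison among those called, with a mean of at least 5 CPM and genotypes that did not overlap, and up to 4 members per list with the smallest p and at least 1 CPM. It took the 5 genes with the smallest p in each direction for the difference between the effects and the 5 with the largest change in each direction between GMP and LSK, and left out unnamed gene models, small RNAs and sex-linked transcripts. Gata3 did not pass in either genotype comparison (adjusted p = 0.401 in LSK and 0.502 in GMP).

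LSK and GMP share title stems, read as the animal, checked by the correlation of deviations from group means across genes. It was 0.29 to 0.43 for T2F3 pairs. For WT pairs it was 0.12 to 0.14, against up to 0.22 between animals, so WT pairs stay unsure. On data simulated from the real means and depths of LSK (15226 genes), 6 of 100 genes changed 2-fold and 45 of 100 changed 4-fold were called, all with the right sign, and 6 of 58 calls were of unchanged genes. An unchanged comparison simulated for GMP gave 0 calls by edgeR. Alternatives were RLE scaling, library sizes without ribosomal protein, histone, mitochondrial and small noncoding RNA genes, no filter, a filter of 5 CPM in 3 libraries, the replicate number, the animal or the library code as a block, only the 6 libraries of a population, limma-voom with quality weights (limma 3.58.1), DESeq2 1.42.0 and leaving out each library. Leaving out both WT replicate 1 libraries, a covariate for the small noncoding RNA share and, for the similarity of LSK and GMP, leaving out each animal were added after the data were seen. Figures were drawn with matplotlib 3.10.9.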

Results

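RNA was sequenced from 2 sorted populations of mouse bone marrow, LSK and GMP, in wild-type (WT) animals and in animals labelled Tet2-/-Flt3ITD (T2F3 in the titles), all C57BL/6 with a donor age of 0.35 years. LSK is the usual name of the lineage-negative, Kit-positive, Sca-1-positive marrow fraction that holds the stem cells, and GMP that of granulocyte-macrophage progenitors, gated on Kit, Fc gamma receptor and CD34. Tet2 encodes a dioxygenase that oxidises methylcytosine in DNA, and Flt3 a receptor tyrosine kinase that an internal tandem duplication (ITD) activates. Each of the 4 groups had 3 libraries, 12 in all, with gene counts as the measured values. Total counts were 17105544, 16176148 and 13316474 in WT LSK replicates 1, 2 and 3, 15978229, 21365867 and 20131393 in T2F3 LSK, 22315312, 21406128 and 17409167 in WT GMP, and 17813359, 23536258 and 23439381 in T2F3 GMP. The labels do not state outright that each replicate came from its own animal, so p-values measure the spread between these libraries, which may in part be technical.

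Tet2 (ENSMUSG00000040943) and Flt3 (ENSMUSG00000042817), the genes the genotype names, were read in every library. Tet2 was at 88.95, 79.8 and 78.96 CPM (counts scaled to the size of the library) in WT LSK and at 42.01, 89.1 and 40.9 CPM in T2F3 LSK, a log2 difference of -0.53 ± 0.28 (SE, n = 3 per group) that did not pass (adjusted p = 0.306). In GMP Tet2 was at 107, 138 and 112 CPM in WT and at 96.35, 88.9 and 66.2 CPM in T2F3 (log2 difference -0.50 ± 0.28, adjusted p = 0.48). Counts over the whole gene do not test the loss of a part of it, so these levels check no label. Flt3 was at 433, 374 and 463 CPM in WT LSK and at 257, 329.6 and 188 CPM in T2F3 LSK (log2 difference -0.71 ± 0.41, adjusted p = 0.349). In GMP, Flt3 rose 4.12-fold, from 20.8, 14.45 and 50.8 CPM in WT to 116, 166 and 72.3 CPM in T2F3 (log2 change 2.04 ± 0.43, adjusted p = 0.0418). That call was lost at adjusted p = 0.0638 and 0.064 without WT LSK replicate 2 or 3, 0.0652 and 0.0573 without T2F3 LSK replicate 1 or 2, 0.143 and 0.146 without WT GMP replicate 1 or 2, 0.106 and 0.183 without T2F3 GMP replicate 1 or 2 and 0.123 without both WT replicate 1 libraries. The difference between the Flt3 effects in LSK and GMP, -2.76 ± 0.59 on the log2 scale, did not pass its own test (adjusted p = 0.163).

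The WT replicate 1 libraries of both populations stood apart from the other WT libraries. Across genes, which are not independent replicates, log2 CPM of WT LSK replicate 1 correlated with replicates 2 and 3 at r = 0.891 and 0.883, against 0.95 between replicates 2 and 3. For WT GMP replicate 1 the values were 0.918 and 0.912, against 0.958. WT replicate 1 had counts in 75.72% of the entries of the count table in LSK and in 71.15% in GMP, and WT replicate 2 in 85.97% and 83.96%. T2F3 replicate 1 also had counts in fewer entries than T2F3 replicates 2 and 3. Its values were 80.81% against 89.78% and 89.02% in LSK, and 80.2% against 89.51% and 88.59% in GMP. In T2F3 LSK replicate 1 correlated with replicates 2 and 3 at 0.939 and 0.929, against 0.949 between those. In T2F3 GMP the values were 0.96 and 0.948, against 0.967. Small noncoding RNA genes and unnamed clones held 23.7 ± 4.395% of the counts in WT LSK, 18.2 ± 11.9% in T2F3 LSK, 19.6 ± 9.82% in WT GMP and 16.95 ± 7.595% in T2F3 GMP (SD, n = 3). In T2F3 replicates 1, 2 and 3 this share was 31.84, 13.26 and 9.546% in LSK and 25.69, 13.24 and 11.93% in GMP. No fit of the genes left out both T2F3 replicate 1 libraries.

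**Figure D1:**
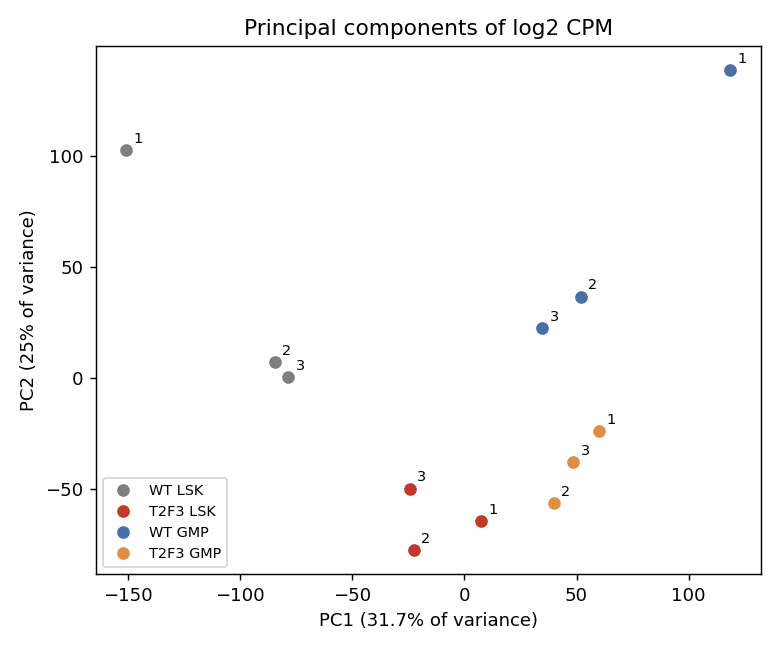
Principal components 1 (x axis, 31.7% of the variance) and 2 (y axis, 25%) of log2 CPM, with a point per library and a marker per group. The WT replicate 1 libraries of LSK and GMP lie apart from the other WT libraries of their population.

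The comparison of T2F3 with WT LSK asks what the combined genotype changes in the fraction that holds the stem cells. Socs2, a feedback inhibitor of cytokine receptor signalling, rose 92.9-fold in T2F3 LSK, from 1.37 ± 0.355 to 129 ± 17.4 CPM (SD, n = 3 per group, log2 change 6.54 ± 0.38 SE, adjusted p = 4.21e-06). Ccn3, a secreted matricellular protein, was at 54.9 ± 8.599 CPM in T2F3 and near 0 in WT, a ratio of 1286 with a 95% counting interval of 356 to 10620 (adjusted p = 3.94e-05). Cp, which encodes ceruloplasmin, was at 22.99 ± 15.4 CPM in T2F3, a ratio of 506 with a 95% counting interval of 139.7 to 4180 (adjusted p = 0.000788). Itgae, the integrin alpha E chain, had no counts in WT LSK and 115 ± 89.4 CPM in T2F3 LSK, at least 587-fold higher against a floor of 3 counts per library (adjusted p = 0.00361). Gdf10, a growth factor of the TGF-beta family, was at least 217-fold higher against the same floor (adjusted p = 0.00272). Kit, the receptor for stem cell factor and a marker of the sort, fell from 883 ± 119.6 to 266 ± 30.8 CPM, 3.31-fold lower (log2 change -1.73 ± 0.21, adjusted p = 0.0015). The other sort markers Ly6a, Cd34 and Fcgr3 did not pass the test in LSK (log2 differences 0.27 ± 0.52, 0.065 ± 0.21 and 0.70 ± 0.46, adjusted p = 0.829, 0.905 and 0.416). For each gene named as higher or lower in a group than in another, all 3 libraries of that group lay above or below all 3 of the other.

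Of 16042 genes tested, 834 changed in LSK, 443 higher and 391 lower in T2F3, and 3451 had an unadjusted p under 0.05. The genotypes did not overlap in 27.9% of genes, against 10% by chance. Without both WT replicate 1 libraries 735 genes passed, of which 528 were among the 834. The labels give the libraries 4 codes of 3 libraries each, whose meaning they do not state and which are too few per code for values within a code. Deviations of libraries from different groups and animals correlated at -0.2 to 0.082 (mean -0.058) with the same code. With different codes this was -0.33 to 0.22 (mean -0.019), so the codes showed no batch by this check. Only the code YOD held LSK libraries of both genotypes, so a code block takes up much of the LSK contrast. Calls lost with it therefore do not by themselves show a batch. With the code as a block 18 genes passed, and Gata2, Ccn3, Cp, Rag1, Zfpm1, Clec12a, Prss34 and Socs2 were the named LSK genes still called. The count was 326, 298 and 533 without WT LSK replicate 1, 2 or 3, 229 and 400 without T2F3 LSK replicate 1 or 2 and 553 without T2F3 GMP replicate 2. Which direction held more genes depended on the fit, with higher and lower genes at 383 and 434 with size factors of DESeq2 in edgeR, 618 and 721 by limma-voom and 870 and 1049 by DESeq2. Lower genes were also more numerous with only the 6 LSK libraries (219 and 255), with the filter of 5 CPM (430 and 450), with the small noncoding RNA share as a covariate (477 and 510), without WT LSK replicate 3 (235 and 298) and without WT GMP replicate 1 (545 and 549).

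Genes of the red cell lineage were lower in T2F3 LSK. Gata1, the transcription factor of erythroid and megakaryocytic cells, fell from 43.5 ± 17.8 to 0.645 ± 0.056 CPM, 66.65-fold lower (SD, n = 3 per group, log2 change -6.06 ± 0.87 SE, adjusted p = 0.00343). Its cofactor Zfpm1 fell from 288 ± 79.3 to 36.6 ± 10.3 CPM, 7.87-fold lower (adjusted p = 0.000257). Car1 and Car2, carbonic anhydrases of red cells, were 171-fold lower and 5.299-fold lower (adjusted p = 0.0045 and 0.00272). Gata2, a transcription factor of stem cells, early erythroid cells and mast cells, fell from 161 ± 12.97 to 19.6 ± 7.82 CPM, 8.203-fold lower (adjusted p = 0.000364). Of 27 erythroid genes tested, 18 fell, 1 rose and 8 did not pass. Counts were 22 falling and 1 rising when adjusted over the list alone. The riser was Tfrc, the transferrin receptor of dividing cells, chosen here after its values were seen (from 61.5 ± 6.59 to 109.8 ± 12.4 CPM, adjusted p = 0.0187). The median log2 change of the list was -5.25, or -5.18 with genes at 0 counts set to their bounds, and its test held (adjusted p = 0.00116 with an estimated correlation). Rising members of this list numbered 0 by edgeR (1 at an unadjusted p under 0.05) without WT LSK replicate 2 or 3 and 0 by edgeR (1 at an unadjusted p under 0.05) without T2F3 LSK replicate 1 or 3. They numbered 1 without both WT replicate 1 libraries and 0 by edgeR (1 at an unadjusted p under 0.05) with the library code as a block. The number of falling members was 9 without WT LSK replicate 1 or 2 and 7, 9 and 10 without T2F3 LSK replicate 1, 2 or 3. There were 16 without both WT replicate 1 libraries and 1 with the library code as a block.

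Some megakaryocyte and platelet genes fell as well, 7 of 23. Itga2b, the integrin CD41 of megakaryocytes and early progenitors, fell from 122 ± 20.4 to 17.1 ± 8.56 CPM, 7.14-fold lower (SD, n = 3 per group, adjusted p = 0.00398). Gp5, a platelet surface glycoprotein, was 53.96-fold lower (adjusted p = 0.00455). The other 16 of this list did not pass, and 10 fell when adjusted over the list alone. The median log2 change was -1.51, a list call with the preset correlation that was lost otherwise (adjusted p = 0.146 with an estimated correlation). Falling members numbered 2, 2 and 3 without WT LSK replicate 1, 2 or 3 and 2, 3 and 2 without T2F3 LSK replicate 1, 2 or 3. With the library code as a block there were 0 by edgeR (10 at an unadjusted p under 0.05), and without both WT replicate 1 libraries 7.

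Most stem cell genes that changed in LSK fell. Hlf, a transcription factor of stem cells, fell from 279 ± 74.1 to 38.8 ± 12.15 CPM, 7.17-fold lower (SD, n = 3 per group, adjusted p = 0.000958). Meis1, a homeobox factor of self-renewal, was 3.06-fold lower (adjusted p = 0.0112). Thy1, a surface protein of stem cells and T cells, rose 12.96-fold, from 13.15 ± 3.69 to 170.3 ± 84.8 CPM (adjusted p = 0.0029). Of 36 stem cell and multipotency genes 11 fell, 1 rose and 24 did not pass, and 21 fell and 1 rose when adjusted over the list alone. The median log2 change was -1.42 and the list was called with the preset correlation alone (adjusted p = 0.117 with an estimated correlation). Of 18 Hox and TALE homeobox genes, Meis1 was the 1 that fell, with 3 falling when adjusted over the list alone. The test of that list held (median -1.37, adjusted p = 0.0157 with an estimated correlation). Falling homeobox genes numbered 3 without WT GMP replicate 1. The library code as a block gave 0 by edgeR (2 at an unadjusted p under 0.05), and leaving out both WT replicate 1 libraries gave 2. Falling stem cell genes numbered 3, 3 and 4 without WT LSK replicate 1, 2 or 3, 3 without T2F3 LSK replicate 1 or 2, 6 without WT GMP replicate 2 and 7 and 6 without T2F3 GMP replicate 1 or 2. As a block, the library code gave 1, against 12 without both WT replicate 1 libraries.

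Some genes of granulocytic and monocytic progenitors changed in T2F3 LSK. Ctsg, cathepsin G of azurophil granules, rose 6.23-fold, from 117 ± 16.2 to 729 ± 363 CPM (SD, n = 3 per group, adjusted p = 0.00471). Clec12a, a lectin receptor of myeloid cells, rose 5.24-fold, from 28.3 ± 7.34 to 148 ± 30.5 CPM (adjusted p = 0.0011). Ly6c2, a surface protein of monocytes, rose 7.47-fold (adjusted p = 0.00978). Csf3r, the receptor for granulocyte colony-stimulating factor, fell from 167 ± 8.06 to 56.45 ± 20.45 CPM, 2.96-fold lower (adjusted p = 0.00514). Of 30 genes of these progenitors and of azurophil granules 8 rose, 1 fell and 21 did not pass. In this list 14 rose and 1 fell when adjusted over the list alone (median log2 change 1.03, adjusted p = 0.157 with an estimated correlation). Rising members numbered 4 without WT LSK replicate 2 and 4 without T2F3 LSK replicate 1. The number was 9 without both WT replicate 1 libraries and 1 with the library code as a block.

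Some monocyte, dendritic cell and MHC class II genes rose in T2F3 LSK, with a wide spread between the 3 libraries. Lgals3, the lectin galectin 3, rose 129-fold (from 0.1505 ± 0.214 to 20.3 ± 15.3 CPM, SD, n = 3 per group, adjusted p = 0.00507), and Adgre1, the F4/80 receptor of macrophages, rose 24.6-fold (adjusted p = 0.00548). Xcr1, a chemokine receptor of cross-presenting dendritic cells, rose 457-fold (adjusted p = 0.00684), to 99.8, 142 and 8.11 CPM in T2F3 replicates 1, 2 and 3. Cd74, the invariant chain of MHC class II, rose 33.6-fold, from 47.2 ± 16.5 to 1585 ± 1278 CPM (adjusted p = 0.0103), with 2134, 2497 and 124 CPM in the T2F3 libraries. H2-Ab1, a beta chain of class II, rose 20.7-fold (adjusted p = 0.0156), a call lost at adjusted p = 0.0667 and 0.0685 without WT LSK replicate 1 or 2, 0.0572 without T2F3 LSK replicate 1 and 0.0574 without both WT replicate 1 libraries. Of 34 monocyte and dendritic cell genes 10 rose and 24 did not pass. There, 23 rose and 2 fell when adjusted over the list alone (median log2 change 2.17, adjusted p = 0.177 with an estimated correlation). Rising members of that list numbered 6 without WT LSK replicate 2 and 6, 6 and 17 without T2F3 LSK replicate 1, 2 or 3. They numbered 9 without both WT replicate 1 libraries and 0 by edgeR (20 at an unadjusted p under 0.05) with the library code as a block. Of 12 MHC class II genes 5 rose and 7 did not pass. Among them 7 rose when adjusted over the list alone (median 2.36, adjusted p = 0.276 with an estimated correlation). Rising class II genes numbered 1, 1 and 3 without WT LSK replicate 1, 2 or 3 and 1, 3 and 9 without T2F3 LSK replicate 1, 2 or 3. There were 1 without both WT replicate 1 libraries and 0 by edgeR (5 at an unadjusted p under 0.05) with the library code as a block.

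Some early lymphoid genes fell in T2F3 LSK, 7 of 28. Satb1, a chromatin organiser of lymphoid progenitors, fell from 206 ± 34.5 to 38.2 ± 22.8 CPM, 5.39-fold lower (SD, n = 3 per group, adjusted p = 0.0086). Notch1, the receptor that starts T cell development, was 2.598-fold lower (adjusted p = 0.0159), a call lost at adjusted p = 0.0556 without WT LSK replicate 1 and 0.068 without T2F3 LSK replicate 1. Rag1, a recombinase of antigen receptor genes, was at 111, 5.94 and 25.6 CPM in WT and near 0 in T2F3 (a ratio of 0.00106 with a 95% counting interval of 0.000219 to 0.00311, adjusted p = 0.0196), a call lost at adjusted p = 0.0697 without WT LSK replicate 1 and 0.091, 0.0684 and 0.0547 without T2F3 LSK replicate 1, 2 or 3. The other 21 early lymphoid and B lineage genes did not pass. Within the list 16 fell and 1 rose when adjusted over the list alone (median log2 change -2.57, adjusted p = 0.117 with an estimated correlation). Falling members numbered 1 without WT LSK replicate 1 and 1, 3 and 4 without T2F3 LSK replicate 1, 2 or 3. With the library code as a block there were 1, and without both WT replicate 1 libraries 5. The following transcripts of B and plasma cells were chosen after their values were seen, and none passed the test over all genes. Ighm, the heavy chain of IgM, was at 2450, 302 and 470.3 CPM in WT replicates 1, 2 and 3 and 264, 353.5 and 132 CPM in T2F3 (adjusted p = 0.084). The joining chain Jchain was at 137, 16.97 and 3.84 CPM in WT and 2.96, 6.299 and 6.296 CPM in T2F3 (adjusted p = 0.0603), and the kappa light chain Igkc at 515, 43.1 and 33.1 CPM in WT and 11.5, 32.2 and 21.1 CPM in T2F3 (adjusted p = 0.0901). Of the B cell receptor subunits, Cd79a was at 5.803, 6.22 and 0.444 CPM in WT and 0, 0.542 and 0.04115 CPM in T2F3 and Cd79b at 14.2, 6.66 and 8.13 CPM in WT and 19.7, 8.84 and 7.74 CPM in T2F3 (adjusted p = 0.108 and 0.749). All of these but Igkc are members of the list.

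Genes of mast cells and basophils went both ways in T2F3 LSK. Prss34, a protease of basophils and mast cells, fell from 9.12 ± 2.96 to 0.346 ± 0.355 CPM, 23.1-fold lower (SD, n = 3 per group, adjusted p = 0.00343). Mcpt8, a protease of basophils, rose 5.52-fold, from 4.31 ± 2.98 to 23.7 ± 8.396 CPM (adjusted p = 0.0105). Of 22 mast cell, basophil and eosinophil genes 5 fell, 1 rose and 16 did not pass, and 8 fell and 3 rose when adjusted over the list alone. The median log2 change was -1.91, or -1.68 with genes at 0 counts set to their bounds (adjusted p = 0.157 with an estimated correlation). Falling members numbered 2 and 3 without WT LSK replicate 2 or 3, 2 without T2F3 LSK replicate 1, 2 or 3, 3 without WT GMP replicate 2 and 3 without T2F3 GMP replicate 2 or 3. The library code as a block gave 2, and leaving out both WT replicate 1 libraries gave 8.

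Targets of STAT5, the transcription factor downstream of many cytokine receptors, also went both ways in LSK. Beside Socs2, its relative Cish rose 7.395-fold, from 15.7 ± 4.55 to 116 ± 33.6 CPM (SD, n = 3 per group, adjusted p = 0.00117). Il2ra, the alpha chain of the interleukin 2 receptor, rose 85.2-fold (adjusted p = 0.00785). Stat5a itself fell from 262 ± 39.6 to 129 ± 9.865 CPM, 2.03-fold lower (adjusted p = 0.0134), a call lost at adjusted p = 0.0509 without WT LSK replicate 2 and 0.0623 without T2F3 LSK replicate 1. Of 24 genes of this list 4 rose, 2 fell and 18 did not pass. Of this list 7 rose and 4 fell when adjusted over the list alone (median log2 change 0.17, adjusted p = 0.177 with an estimated correlation). Rising members numbered 4 without both WT replicate 1 libraries and 1 with the library code as a block. Its falling members numbered 1, 0 by edgeR (4 at an unadjusted p under 0.05) and 1 without WT LSK replicate 1, 2 or 3, 0 by edgeR (4 at an unadjusted p under 0.05) and 1 without T2F3 LSK replicate 1 or 2 and 1 without T2F3 GMP replicate 2. As a block, the library code gave 0 by edgeR (4 at an unadjusted p under 0.05), against 1 without both WT replicate 1 libraries.

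Immediate early genes, which cells induce within minutes of a stimulus or of handling, fell in part in T2F3 LSK. Ier2 fell from 378 ± 137 to 74.8 ± 22.7 CPM, 5.05-fold lower (SD, n = 3 per group, adjusted p = 0.00361). Rhob, a small GTPase, was 2.535-fold lower (adjusted p = 0.00689), and Ppp1r15a, a phosphatase subunit induced by stress, 4.71-fold lower (adjusted p = 0.00919). Of 30 genes 7 fell and 23 did not pass. Within this list 14 fell and 1 rose when adjusted over the list alone (median log2 change -1.36, adjusted p = 0.278 with an estimated correlation). Falling members numbered 3 and 4 without WT LSK replicate 2 or 3, 3 without T2F3 LSK replicate 1 or 3 and 11 without WT GMP replicate 1. The number was 12 without both WT replicate 1 libraries and 0 by edgeR (14 at an unadjusted p under 0.05) with the library code as a block.

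**Figure D2:**
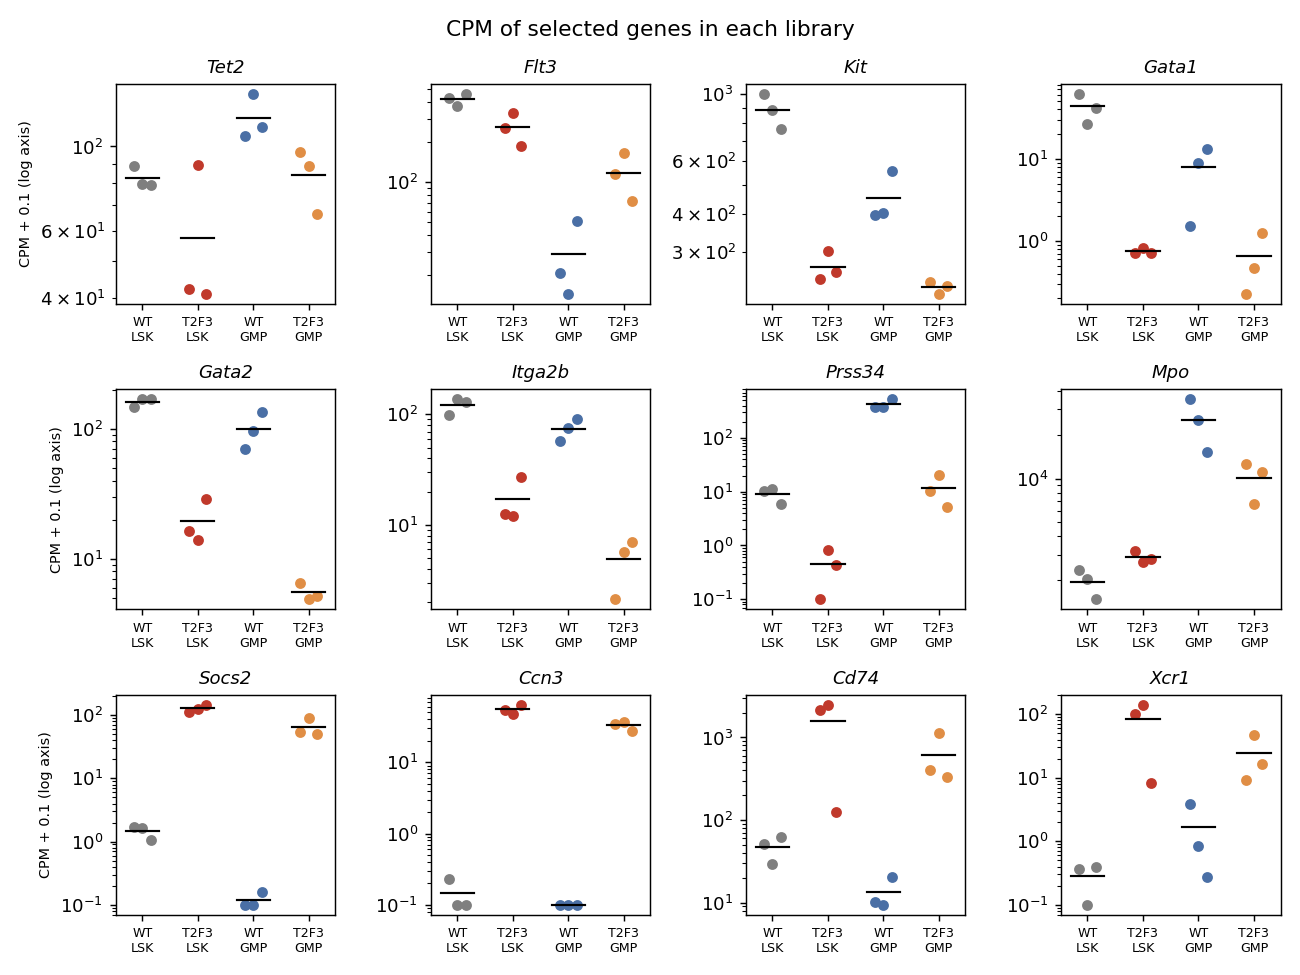
CPM plus 0.1 on a log axis for 12 genes, with a point per library, a bar at each group mean and the 4 groups of 3 libraries along the x axis. The mean of Socs2 was 1.37 CPM in WT LSK and 129 CPM in T2F3 LSK, and the T2F3 LSK libraries of Xcr1 were at 99.8, 142 and 8.11 CPM.

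In GMP the same question was asked of committed myeloid progenitors. Socs2 was at 64.98 ± 22.45 CPM in T2F3 GMP and near 0 in WT GMP, a ratio of 3817 with a 95% counting interval of 685 to 150800 (SD, n = 3 per group, adjusted p = 5.43e-07). Cish rose 15.7-fold, from 3.18 ± 1.32 to 49.85 ± 11.9 CPM (adjusted p = 0.000266). Pim1, a kinase gene induced by STAT5, rose 3.36-fold, from 111 ± 6.45 to 372 ± 71.9 CPM (adjusted p = 0.00121). Of 24 STAT5 targets these 3 rose and 21 did not pass, and 5 rose and 2 fell when adjusted over the list alone. The median log2 change was 0.185, or 0.073 with genes at 0 counts set to their bounds (adjusted p = 0.194 with an estimated correlation). Rising members numbered 3 without both WT replicate 1 libraries and 3 with the library code as a block. Ccn3 had no counts in WT GMP and 33.1 ± 4.87 CPM in T2F3 GMP, at least 205.5-fold higher (adjusted p = 4.53e-05). Cp rose 849-fold to 64.7 ± 17.8 CPM (adjusted p = 0.000376). Tcrg-C1, a constant segment of the T cell receptor gamma chain whose reads resemble those of its sister segments, was at least 67.8-fold higher (adjusted p = 0.00542). Kit fell from 451 ± 89.5 to 228.5 ± 10.35 CPM in GMP, 1.97-fold lower (adjusted p = 0.0431), a call lost at adjusted p = 0.0716 and 0.0588 without WT LSK replicate 2 or 3, 0.0517, 0.0603 and 0.0506 without T2F3 LSK replicate 1, 2 or 3, 0.0666, 0.103 and 0.0956 without WT GMP replicate 1, 2 or 3 and 0.133, 0.206 and 0.111 without T2F3 GMP replicate 1, 2 or 3. The sort markers Ly6a, Cd34 and Fcgr3 did not pass the test in GMP (log2 differences 0.90 ± 0.54, -0.098 ± 0.21 and -1.39 ± 0.42, adjusted p = 0.529, 0.912 and 0.15).

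Of the genes tested, 183 changed in GMP, 109 higher and 74 lower in T2F3, and 2176 had an unadjusted p under 0.05. The genotypes did not overlap in 21.7% of genes, against 10% by chance. Without both WT replicate 1 libraries 194 passed, of which 112 were among the 183, and with the library code as a block 39 passed. With that block 28 of the 44 named genes called in GMP lost the call. The count of changed genes was 99 and 61 without WT GMP replicate 1 or 2 and 80, 55 and 103 without T2F3 GMP replicate 1, 2 or 3. Higher and lower genes numbered 359 and 473 by limma-voom, 48 and 51 without WT GMP replicate 1 and 26 and 35 without WT GMP replicate 2, so that the direction with more genes turned in these fits.

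Genes of mast cells and red cells were lower as lists in T2F3 GMP, and some megakaryocyte genes fell. Prss34 fell from 427 ± 86.7 to 11.7 ± 7.61 CPM, 36.5-fold lower (SD, n = 3 per group, adjusted p = 0.00103). Ms4a2, the beta chain of the IgE receptor, was 23.4-fold lower (adjusted p = 0.00567). Hdc, which makes histamine, was 6.775-fold lower (adjusted p = 0.00332), and Gata2 fell from 99.97 ± 32.95 to 5.42 ± 0.859 CPM, 18.5-fold lower (adjusted p = 4.53e-05). Of 22 mast cell, basophil and eosinophil genes 5 fell and 17 did not pass. In this list 16 fell when adjusted over the list alone (median log2 change -3.19, adjusted p = 0.00388 with an estimated correlation). Falling members of that list numbered 8 without both WT replicate 1 libraries and 3 with the library code as a block. Of 27 erythroid genes 6 fell and 21 did not pass. Here 12 fell when adjusted over the list alone (median -2.81, or -2.51 with genes at 0 counts set to their bounds, adjusted p = 0.00222 with an estimated correlation). Among them Car2 was 4.05-fold lower (from 24.9 ± 1.88 to 6.13 ± 1.66 CPM, adjusted p = 0.0135), a call lost at adjusted p = 0.0708 and 0.086 without T2F3 GMP replicate 1 or 2. Gata1 fell from 7.803 ± 5.904 to 0.553 ± 0.5403 CPM, 13.5-fold lower (adjusted p = 0.0431), a call lost at adjusted p = 0.0624 and 0.0684 without WT LSK replicate 2 or 3, 0.068 and 0.0656 without T2F3 LSK replicate 1 or 2, 0.121 and 0.0883 without WT GMP replicate 2 or 3 and 0.136 and 0.206 without T2F3 GMP replicate 1 or 2. Falling erythroid members numbered 2 without WT LSK replicate 3, 2 and 3 without WT GMP replicate 2 or 3 and 2, 0 by edgeR (18 at an unadjusted p under 0.05) and 3 without T2F3 GMP replicate 1, 2 or 3. They numbered 7 without both WT replicate 1 libraries and 1 with the library code as a block. Itga2b and Gfi1b, a transcription factor of megakaryocytes and red cells, were the 2 of 23 megakaryocyte genes that fell, 15.2-fold lower and 35.5-fold lower (adjusted p = 0.00121 and 0.00751). That list had 13 falling when adjusted over the list alone (median -2.52, or -1.43 with genes at 0 counts set to their bounds, adjusted p = 0.112 with an estimated correlation). Falling megakaryocyte genes numbered 5 without T2F3 LSK replicate 3 and 5 without WT GMP replicate 1. There were 5 without both WT replicate 1 libraries and 1 with the library code as a block.

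Some MHC class II genes rose in T2F3 GMP, and stem cell and granule genes showed few calls. Cd74 rose 46.8-fold, from 13.2 ± 6.18 to 619 ± 438 CPM (SD, n = 3 per group, adjusted p = 0.0153), a call lost at adjusted p = 0.0678 and 0.082 without WT GMP replicate 1 or 2 and 0.067 without both WT replicate 1 libraries. Of 12 class II genes 5 rose and 7 did not pass. Among these 9 rose when adjusted over the list alone (median log2 change 2.83, adjusted p = 0.196 with an estimated correlation). Rising class II genes numbered 3 without WT LSK replicate 2, 3 without T2F3 LSK replicate 1 or 2, 0 by edgeR (8 at an unadjusted p under 0.05), 0 by edgeR (8 at an unadjusted p under 0.05) and 1 without WT GMP replicate 1, 2 or 3 and 2 and 1 without T2F3 GMP replicate 1 or 2. With the library code as a block there were 0 by edgeR (7 at an unadjusted p under 0.05), and without both WT replicate 1 libraries 0 by edgeR (9 at an unadjusted p under 0.05). Cd74 was at 399.7, 1123 and 333.5 CPM in T2F3 GMP replicates 1, 2 and 3. The dendritic cell marker Xcr1 was at 3.75, 0.7375 and 0.1745 CPM in WT and 9.12, 46.8 and 16.3 CPM in T2F3 GMP. Clec9a, of the same cells, was at 0, 0.0868 and 3.897 CPM in WT and 13.2, 51.7 and 11.6 CPM in T2F3. Their marker Itgax was at 1.43, 2.86 and 1.86 CPM in WT and 7.98, 19.9 and 5.61 CPM in T2F3. These 3 did not pass the test in GMP (adjusted p = 0.113, 0.208 and 0.21), nor did the macrophage markers Adgre1, at 8.34, 9.15 and 8.375 CPM in WT and 29.6, 22.2 and 40.8 CPM in T2F3, and Apoe, at 20.85, 17.35 and 26.8 CPM in WT and 1.27, 4.79 and 4.41 CPM in T2F3 (adjusted p = 0.196 and 0.102). Of these markers Clec9a, Itgax, Adgre1 and Apoe were chosen for GMP after their values were seen. Slamf7, a receptor of immune cells, was the 1 of 34 monocyte and dendritic cell genes that rose in GMP, from 0.4065 ± 0.439 to 20.7 ± 17.7 CPM (adjusted p = 0.0446), a call lost at adjusted p = 0.0647 and 0.064 without WT LSK replicate 2 or 3, 0.0746 and 0.0657 without T2F3 LSK replicate 1 or 2, 0.126, 0.173 and 0.0687 without WT GMP replicate 1, 2 or 3, 0.0781, 0.169 and 0.0627 without T2F3 GMP replicate 1, 2 or 3 and 0.0949 without both WT replicate 1 libraries. In its list 4 rose when adjusted over the list alone (median 0.91, adjusted p = 0.384 with an estimated correlation). Rising monocyte and dendritic cell genes numbered 2 without WT LSK replicate 1 and 4 without T2F3 LSK replicate 3. Without any other single library they numbered 0 by edgeR (7 to 13 at an unadjusted p under 0.05). Those at an unadjusted p under 0.05 were 13 and 12 without WT LSK replicate 2 or 3 and 12 and 11 without T2F3 LSK replicate 1 or 2. They were 10, 9 and 11 without WT GMP replicate 1, 2 or 3 and 11, 7 and 12 without T2F3 GMP replicate 1, 2 or 3. The library code as a block gave 0 by edgeR (8 at an unadjusted p under 0.05), and leaving out both WT replicate 1 libraries gave 0 by edgeR (10 at an unadjusted p under 0.05). Thy1 rose 24.6-fold, from 2.535 ± 0.797 to 62.15 ± 45.25 CPM (adjusted p = 0.0016). It was the 1 stem cell gene of 36 that rose, while 3 fell and 32 did not pass (4 and 10 when adjusted over the list alone). The median of that list was 0.0027, or -0.032 with genes at 0 counts set to their bounds, its mean -0.29, so median and mean differed in sign, and it was not called (adjusted p = 0.139 with the preset correlation). Falling stem cell genes numbered 1 without T2F3 GMP replicate 1 or 2. As a block, the library code gave 1, against 4 without both WT replicate 1 libraries. Csf3r was the 1 of 30 progenitor and granule genes that changed, 2.91-fold lower (from 154 ± 16.7 to 52.97 ± 10.01 CPM, adjusted p = 0.0107), a call lost at adjusted p = 0.0717 without T2F3 GMP replicate 2. In that list 10 fell when adjusted over the list alone (median -0.77, adjusted p = 0.257 with an estimated correlation). Falling granule genes numbered 0 by edgeR (8 at an unadjusted p under 0.05) without T2F3 GMP replicate 2. The number was 1 without both WT replicate 1 libraries and 0 by edgeR (9 at an unadjusted p under 0.05) with the library code as a block. Mpo, the myeloperoxidase of those granules, was at 25180 ± 10030 CPM in WT and 10120 ± 3051 CPM in T2F3 GMP, which did not pass (log2 difference -1.32 ± 0.42, adjusted p = 0.17).

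**Figure D3:**
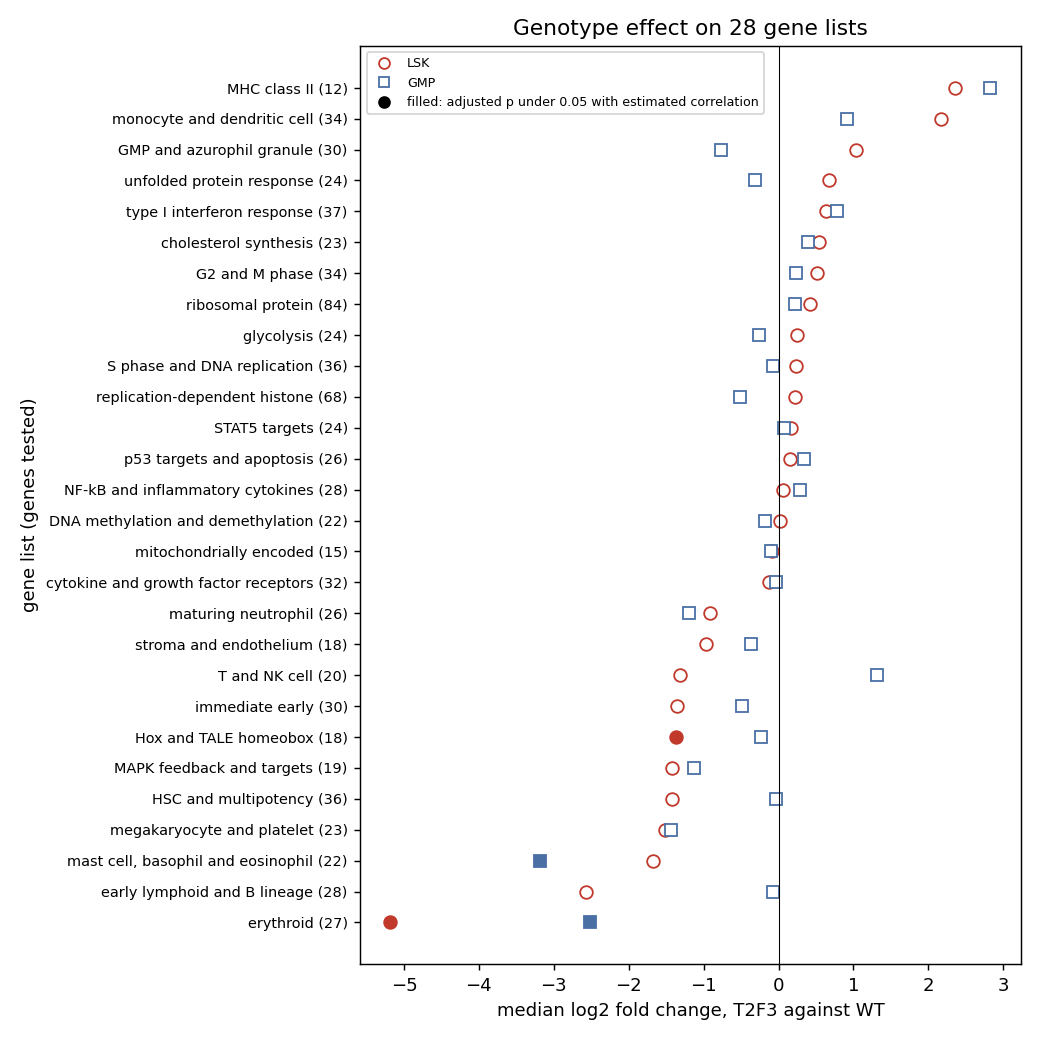
Median log2 fold change (x axis, T2F3 over WT, genes at 0 counts at their bounds) of the 28 gene lists (y axis) in LSK (circles) and GMP (squares), filled where the adjusted p with an estimated correlation was under 0.05. The erythroid list lay at -5.18 in LSK and -2.51 in GMP.

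Many genes were called in both populations, whose libraries are separate but come from the same animals by their titles. Among them were Socs2, Cish, Ccn3, Cp and Thy1, which rose, and Gata2, Itga2b, Prss34 and Csf3r, which fell. Of the 443 genes higher in LSK and the 109 higher in GMP, 60 were shared, against 3.01 for independent lists (Fisher's exact test, two-sided, p = 4.42e-65). Of the 391 and 74 lower genes 47 were shared, against 1.8 (Fisher's exact test, p = 6.07e-58), and 2 genes, Mcpt8 and Gprc5b, were called in opposite directions. Genes are not independent replicates, and part of the excess may come from the shared animals. The Gata2 effect, -3.04 ± 0.31 in LSK and -4.21 ± 0.33 in GMP on the log2 scale (SE), did not pass the test of the difference (adjusted p = 0.42).

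The genotype effect was tested for a difference between LSK and GMP by an interaction term. Mcpt8 rose 5.52-fold in LSK (from 4.31 ± 2.98 to 23.7 ± 8.396 CPM, SD, n = 3 per group, adjusted p = 0.0105) and was at 111 ± 8.82 CPM in WT GMP and 24.8 ± 3.89 CPM in T2F3 GMP. The effects differed by 4.625 ± 0.62 on the log2 scale (SE, adjusted p = 0.0389). Enah, an actin regulator, Cers6, a ceramide synthase, and Sema4a, a semaphorin, were the other genes called, with differences of 4.16 ± 0.55, 1.865 ± 0.26 and 3.09 ± 0.45 (adjusted p = 0.0389, 0.047 and 0.047). Enah went from 0.249 ± 0.0949 to 52.6 ± 18.9 CPM in LSK and from 1.93 ± 0.553 to 21.9 ± 3.998 CPM in GMP. The signed effect was higher in LSK for all 4 in this fit, and 1519 genes had an unadjusted p under 0.05. With other scalings the numbers of genes with a higher and a lower effect in LSK were 4 and 2 (size factors of DESeq2) and 4 and 1 (library sizes without ribosomal protein, histone, mitochondrial and small noncoding RNA genes). EdgeR called 0 with the animal as a block, where 1858 genes had an unadjusted p under 0.05, and 0 with the library code as a block, where 641 had. It called 1 without both WT replicate 1 libraries, while limma-voom called 23 (11 and 12) and DESeq2 190 (74 and 116) with all libraries, both with more genes on the lower side. The count was 1, 0 and 1 without WT LSK replicate 1, 2 or 3, 0 without T2F3 LSK replicate 1, 2 or 3, 0, 0 and 10 without WT GMP replicate 1, 2 or 3 and 0, 0 and 1 without T2F3 GMP replicate 1, 2 or 3. The gene called without T2F3 GMP replicate 3 had the lower effect in LSK. In the fits without a single library that called 0, 1030 to 1672 genes had an unadjusted p under 0.05. Mcpt8 lost its call at adjusted p = 0.144 without WT LSK replicate 2, 0.0913, 0.0602 and 0.0743 without T2F3 LSK replicate 1, 2 or 3, 0.102 and 0.165 without WT GMP replicate 1 or 2, 0.132, 0.122 and 0.0518 without T2F3 GMP replicate 1, 2 or 3 and 0.0529 with the animal as a block. Enah lost its call at adjusted p = 0.101, 0.144 and 0.094 without WT LSK replicate 1, 2 or 3, 0.0538, 0.0626 and 0.0743 without T2F3 LSK replicate 1, 2 or 3, 0.102 and 0.165 without WT GMP replicate 1 or 2, 0.132, 0.122 and 0.0518 without T2F3 GMP replicate 1, 2 or 3, 0.0529 with the animal as a block and 0.127 without both WT replicate 1 libraries. Cers6 lost its call at adjusted p = 0.101, 0.144 and 0.137 without WT LSK replicate 1, 2 or 3, 0.0538, 0.0653 and 0.0743 without T2F3 LSK replicate 1, 2 or 3, 0.102 and 0.166 without WT GMP replicate 1 or 2, 0.132, 0.122 and 0.0518 without T2F3 GMP replicate 1, 2 or 3, 0.0529 with the animal as a block and 0.127 without both WT replicate 1 libraries. Sema4a lost its call at adjusted p = 0.101, 0.144 and 0.0666 without WT LSK replicate 1, 2 or 3, 0.11, 0.0653 and 0.0743 without T2F3 LSK replicate 1, 2 or 3, 0.111 and 0.166 without WT GMP replicate 1 or 2, 0.132, 0.122 and 0.0588 without T2F3 GMP replicate 1, 2 or 3, 0.109 with the animal as a block and 0.127 without both WT replicate 1 libraries.

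The comparison of GMP with LSK in WT animals asks how the populations differ without the genotype. Ly6a, which encodes Sca-1, was 10.3-fold lower in WT GMP, from 22.9 ± 4.57 to 2.22 ± 1.17 CPM (SD, n = 3 per group, adjusted p = 0.00273), and Fcgr3, an Fc gamma receptor, was 46.1-fold higher, from 2.67 ± 1.3 to 123 ± 33.5 CPM (adjusted p = 8.9e-05). Kit and Cd34 were 1.96-fold lower and 1.67-fold lower in WT GMP (adjusted p = 0.00958 and 0.039). The Kit call was lost at adjusted p = 0.0767 without both WT replicate 1 libraries. That of Cd34 was lost at adjusted p = 0.109 and 0.113 without WT LSK replicate 2 or 3, 0.0866, 0.14 and 0.0504 without WT GMP replicate 1, 2 or 3, 0.0579, 0.0575 and 0.053 without T2F3 GMP replicate 1, 2 or 3 and 0.0529 without both WT replicate 1 libraries. The sort label writes Sca-1-negative for both populations. Hlf was 23.2-fold lower (from 279 ± 74.1 to 12.02 ± 2.65 CPM, adjusted p = 7.37e-05) and Flt3 14.8-fold lower (adjusted p = 0.000315). Ms4a3, a membrane protein of granulocyte progenitors, was 32.9-fold higher (from 11.7 ± 2.63 to 386 ± 151 CPM, adjusted p = 0.00015), and Prg2, a granule protein of eosinophils, 216-fold higher (adjusted p = 0.00251). Of 36 stem cell genes 28 were lower and 8 did not pass (34 lower when adjusted over the list alone, median log2 difference -3.41, adjusted p = 0.0083 with an estimated correlation). This number was 25 without both WT replicate 1 libraries and 23 with the library code as a block. Of 30 progenitor and granule genes 26 were higher and 4 did not pass (27 when adjusted over the list alone, median 3.15, adjusted p = 0.0132 with an estimated correlation). This number was 22 without both WT replicate 1 libraries and 22 with the library code as a block. Of 22 mast cell genes 12 were higher and 10 did not pass (15 higher and 2 lower when adjusted over the list alone, median 4.04, adjusted p = 0.0135 with an estimated correlation). This number was 12 without both WT replicate 1 libraries and 10 with the library code as a block.

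In all, 2100 genes differed between WT GMP and LSK, 918 higher and 1182 lower in GMP, and 4535 had an unadjusted p under 0.05. Of the erythroid genes 10 of 27 were lower in WT GMP and 1 higher (15 and 1 when adjusted over the list alone, adjusted p = 0.0083 with an estimated correlation). Car2 was 15.5-fold lower (adjusted p = 7.95e-05). Lower members numbered 4 without WT LSK replicate 1 and 6 without WT GMP replicate 2. They numbered 7 without both WT replicate 1 libraries and 5 with the library code as a block. Unfolded protein response genes had 15 of 24 higher and 1 lower (16 and 2 when adjusted over the list alone, adjusted p = 0.0269 with an estimated correlation). Higher members of this list numbered 13 without both WT replicate 1 libraries and 11 with the library code as a block. Lower members of it numbered 0 by edgeR (2 at an unadjusted p under 0.05) without WT LSK replicate 2 and 0 by edgeR (1 at an unadjusted p under 0.05) and 2 without WT GMP replicate 1 or 3. There were 1 without both WT replicate 1 libraries and 1 with the library code as a block. The count of all genes was 1367 and 1234 without WT GMP replicate 1 or 2, 1296 without both WT replicate 1 libraries and 974 with the library code as a block. Groups did not overlap in 31.5% of genes, against 10% by chance.

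In T2F3 animals GMP and LSK differed in 156 genes, 44 higher and 112 lower in GMP. Fcgr3 was 10.8-fold higher in GMP, from 4.305 ± 1.08 to 46.9 ± 26.4 CPM (SD, n = 3 per group, adjusted p = 0.00389), and Hlf 9.67-fold lower (from 38.8 ± 12.15 to 3.98 ± 1.52 CPM, adjusted p = 0.00129). Ly6a was 6.66-fold lower in GMP (adjusted p = 0.0388), a call lost at adjusted p = 0.0581 and 0.069 without WT LSK replicate 2 or 3, 0.136 and 0.08 without T2F3 LSK replicate 1 or 2 and 0.0775, 0.158 and 0.194 without T2F3 GMP replicate 1, 2 or 3. Hdc was 11.9-fold higher and Prss34 29.5-fold higher (adjusted p = 0.00129 and 0.00379), and Dntt, the terminal transferase of lymphoid progenitors, was 128-fold lower (adjusted p = 0.00129). Of 36 stem cell genes 13 were lower and 23 did not pass (24 lower when adjusted over the list alone, median log2 difference -1.7, adjusted p = 0.0161 with an estimated correlation). This number was 4, 4 and 5 without T2F3 GMP replicate 1, 2 or 3. With the library code as a block there were 0 by edgeR (22 at an unadjusted p under 0.05), and without both WT replicate 1 libraries 18. Of 30 progenitor and granule genes 2 were higher and 28 did not pass (15 higher when adjusted over the list alone, median 1.02, adjusted p = 0.0234 with an estimated correlation). This number was 5 without WT LSK replicate 1, 1 without T2F3 LSK replicate 2 or 3, 7 and 4 without WT GMP replicate 1 or 3, 1 without T2F3 GMP replicate 1 or 3 and 10 with the animal as a block. The library code as a block gave 0 by edgeR (14 at an unadjusted p under 0.05), and leaving out both WT replicate 1 libraries gave 9. An unadjusted p under 0.05 was seen for 1281 genes, and the groups did not overlap in 15.3% of genes, against 10% by chance. The count of all genes was 96 and 61 without T2F3 LSK replicate 2 or 3, 256 without WT GMP replicate 1 and 47, 67 and 52 without T2F3 GMP replicate 1, 2 or 3. It was 413 without both WT replicate 1 libraries and 0 by edgeR with the library code as a block (748 at an unadjusted p under 0.05), against 561 by limma-voom and 522 by DESeq2 without that block.

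LSK and GMP of a title stem were set side by side in both genotypes. Hlf differed between GMP and LSK by -4.54 ± 0.35 in WT and by -3.27 ± 0.34 in T2F3 on the log2 scale (SE), which did not pass the test of the difference (adjusted p = 0.415). Of the 2100 genes called between WT GMP and LSK, 2021 had a smaller fitted difference in T2F3 and 1882 the same sign (median absolute log2 difference 1.73 in WT and 0.65 in T2F3). These genes were chosen on WT, which favours large differences in WT. Of the 156 genes called between T2F3 populations, 105 were also smaller in T2F3 than in WT (medians 2.65 and 3.22). Between LSK and GMP with the same title stem, r of log2 CPM across genes, which are not independent replicates, was 0.856 ± 0.064 in WT and 0.94 ± 0.015 in T2F3 (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). The WT values were 0.783, 0.883 and 0.902 for replicates 1, 2 and 3, and the T2F3 values 0.924, 0.954 and 0.943. Without WT replicate 1, a choice made after the data were seen, the WT mean was 0.892 and the difference between genotypes 0.0482, against 0.0846 with all animals. Each T2F3 library had counts in more entries than the WT library of the same number and population. In LSK this was 80.81, 89.78 and 89.02% against 75.72, 85.97 and 83.7%. In GMP it was 80.2, 89.51 and 88.59% against 71.15, 83.96 and 84.99%. Since r may depend on this, a greater likeness of LSK and GMP in T2F3 was not told apart from it.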

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

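The tests of co-sorted erythroid cells, of B cells, macrophages and dendritic cells and of handling were chosen only after the result was seen, as was leaving out both WT replicate 1 libraries and the covariate, and the others were not.

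Mcpt8, Enah, Cers6 and Sema4a stood out because their genotype effect differed between LSK and GMP by the interaction test of edgeR, by 4.625, 4.16, 1.865 and 3.09 on the log2 scale (LSK minus GMP, n = 3 per group). That fit did not use the pairing of LSK and GMP by title stem. With the animal as a block none of the 4 was called, and each lost its call in some fit without a library. Cers6 was at 50.4 ± 2.74 CPM in WT LSK, 222 ± 37.5 in T2F3 LSK, 220.3 ± 16.5 in WT GMP and 267 ± 41.2 CPM in T2F3 GMP, and Sema4a at 4.48 ± 1.68, 60.1 ± 15.6, 47.5 ± 13.5 and 75.02 ± 17.3 CPM (SD). The signed log2 effect of T2F3 over WT was higher in LSK than in GMP with the preset correlation for these lists (median difference): granule (1.84, adjusted p = 5.98e-24), monocyte and dendritic cell (0.956, adjusted p = 0.00255), mast cell (1.18, adjusted p = 1.2e-05), S phase (0.474, adjusted p = 4.91e-05), G2 and M phase (0.243, adjusted p = 0.00479), unfolded protein response (0.952, adjusted p = 1.64e-09), glycolysis (0.659, adjusted p = 0.000526), ribosomal protein (0.325, adjusted p = 0.0231) and histone (0.674, adjusted p = 0.000271). For mast cell genes this was a smaller fall in LSK than in GMP (medians -1.91 and -3.19), and for histone genes medians of 0.22 and -0.51. It was lower in LSK for stem cell (-1.24, adjusted p = 1.58e-07), erythroid (-1.16, adjusted p = 0.00129), early lymphoid (-1.41, adjusted p = 0.000121), T and NK cell (-0.86, adjusted p = 0.0247), MAPK feedback (-0.372, adjusted p = 0.00479), immediate early (-0.919, adjusted p = 3.96e-05) and Hox (-1.14, adjusted p = 0.000219). None of these 16 lists was called by camera with an estimated correlation, where the smallest adjusted p were 0.0655 for the granule and Hox lists and 0.0753 for the unfolded protein response.

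Erythroid genes were lower in T2F3 LSK, with a median log2 change of -5.25. The tables argue against the WT replicate 1 libraries and the small noncoding RNA share as the whole cause, since without both of these libraries the median was -5.23 (list adjusted p = 1.06e-27 with the preset correlation), and with the share as a covariate it was -5.88 (adjusted p = 1.5e-21). Fewer co-sorted erythroid cells of a single kind in T2F3 would lower their genes alike, and the SD of the log2 changes over 14 members was 2.61 times their median SE, which leaves this open because a baseline in the other cells also spreads the changes. The sort removes Ter119-positive cells, and Gata2 and Zfpm1, which fell as well, are expressed by stem and progenitor cells themselves. A change of the genotype within LSK cells stays open and could not be tested apart from a change in the mixture of cells.

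Of 12 MHC class II genes 5 rose in T2F3 LSK, with Cd74 at 2134, 2497 and 124 CPM in the 3 libraries, in a list called with the preset correlation alone (adjusted p = 0.276 with an estimated correlation). B cells may be a source, though the sort removes B220-positive cells, and the 7 tested of their 9 markers (7 also in other lists) had a median log2 change of -2.1 but went both ways, with the most abundant, Cd79b, at 9.68 ± 4.02 CPM in WT and 12.1 ± 6.597 in T2F3 (SD, n = 3). Macrophages, which the Mac-1 antibody removes, stay open too, with a median of -3 over 8 of 10 markers (6 in other lists) that also went both ways, Adgre1 at 4.62 ± 0.74 and the most abundant, Apoe, at -3.42 ± 0.73 (SE, 30.7 ± 16.5 and 2.84 ± 2.93 CPM). Dendritic cells or their progenitors in the gate are a candidate source, since 10 markers (6 in other lists) had a median of 2.64. Xcr1, Clec9a, Batf3 and Zbtb46 were low in T2F3 LSK replicate 3 as Cd74 was (Clec9a 62.6, 113 and 3.46 CPM). The markers went both ways, and only Xcr1 and Clec9a passed. Siglech (-1.45 ± 1.53) and Clec10a (-0.70 ± 0.76) fell by less than their SE. Flt3 (-0.71 ± 0.41) cannot test for these cells, at 374 to 463 CPM in WT LSK, which nearly lacked Xcr1 and Clec9a. Itgax was at 43.5, 51.9 and 2.14 CPM in T2F3 LSK, against 6.198, 4.2 and 6.949 CPM in WT. Class II expression by the LSK cells themselves was not tested apart from this.

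Of 30 immediate early genes 7 fell in T2F3 LSK (median log2 change -1.36). A single WT LSK library is not the whole cause, since without replicate 1, 2 or 3 the median was -1.34, -0.965 and -1.5 and the list stayed called with the preset correlation (the highest adjusted p was 8.87e-05, without replicate 2), although the list with all libraries was not called otherwise (adjusted p = 0.278 with an estimated correlation). Handling of the marrow that differed between animals could move LSK and GMP of an animal alike, and the median in GMP was -0.488, with p = 0.254 for the difference (camera, estimated correlation), which leaves handling open. An effect of the genotype on these genes stays open too.

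All 10 splits of the 6 libraries behind each comparison, or of the 6 animals for the difference, were run, too few for a share under 0.05. The real split was the 1 with the largest count each time, 834 genes in LSK, 183 in GMP, 4 for the difference, 2100 between populations in WT and 156 in T2F3, and the highest count of the other splits was 0 by edgeR in each. Every other split mixed both genotypes, or both populations, within its groups. A real difference then adds to the spread within groups and lowers the count, so these splits cannot decide whether the real counts arose by chance.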

How the results depend on the processing

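Leaving out both WT replicate 1 libraries or an animal and the covariate were chosen only after the result was seen, and the other alternatives before the data were examined. Of 96 named genes called in LSK 50 lost the call in some fit without a library, of 44 in GMP 28, of 4 for the difference 4, of 110 between WT populations 31 and of 31 between T2F3 populations 20, and none of these calls changed sign. Over all alternatives, calls of named genes were lost 408 times in LSK, 231 in GMP, 54 for the difference, 191 and 135 between populations, and gained 66, 110, 56, 24 and 97 times. Changed genes, in the order LSK, GMP, difference, WT populations and T2F3 populations, numbered 834, 183, 4, 2100 and 156. They numbered 18, 39, 0, 974 and 0 with the library code as a block, 1339, 832, 23, 3186 and 561 with limma-voom and 1919, 789, 190, 3225 and 522 with DESeq2. Without both WT replicate 1 libraries they numbered 735, 194, 1, 1296 and 413. With only the 6 libraries of the population LSK gave 474 and GMP 124, with 4 residual degrees of freedom. The difference gave 7 genes with the filter of 5 CPM, 0 by edgeR with the animal as replicate block and 10 with the covariate. The animal block gave 2354 and 194 genes between populations, each within 1.5 times of the count without it. WT and T2F3 libraries share only a number, with a correlation of deviations across genes of -0.012 to 0.19, and 5 of 12 libraries correlated best with their own number, and with the number as replicate block LSK gave 907 and GMP 185 genes. Leaving out a library gave 229 to 1094 genes in LSK, 55 to 250 in GMP, 0 to 10 for the difference, 1234 to 2090 in WT populations and 47 to 256 in T2F3 populations. Called lists fell to 2 in LSK, 2 in GMP and 0 for the difference by camera with an estimated correlation, from 20, 14 and 16. Named log2 differences that did not pass and changed sign were, in LSK, Ly6a (0.27 here, -0.34 to 0.64 without a library, -0.0335 with voom) and Cd34 (0.065 here, -0.06987 to 0.19 without a library, -0.071 with voom, -0.086 without both WT replicate 1), and in GMP Cd34 (-0.098 here, -0.19 to -0.016 without a library, 0.025 with voom). For the difference they were Tet2 (-0.022 here, -0.49 to 0.17 without a library, 0.23 with the code block, 0.10 with voom, 0.10 without both WT replicate 1), Cd34 (0.16 here, 0.026 to 0.29 without a library, -0.096 with voom, -3.926e-05 without both WT replicate 1), Ciita (-1.24 here, -2.21 to -0.43 without a library, 0.34 with the code block), mt-Nd2 (0.20 here, -0.17 to 0.48 without a library, -0.051 with the code block), mt-Nd6 (0.26 here, -0.073 to 0.60 without a library) and mt-Co2 (0.17 here, -0.175 to 0.41 without a library, -0.13 with the code block). Between T2F3 populations they were Gata1 (-0.17 here, -1.27 to 0.24 without a library), Rrm2 (0.36 here, -0.0012 to 0.52 without a library), Rpl15 (0.35 here, -0.12 to 0.57 without a library), Hist1h1b (-0.42 here, -0.68 to 0.28 without a library), Hist1h4k (-0.69 here, -1.12 to 0.63 without a library, 0.037 with the code block, 0.053 with voom) and Hist1h2be (-0.52 here, -0.85 to 0.43 without a library, 0.25 with the code block). Fewer libraries and degrees of freedom are part of the fits that leave libraries out or add a block, and otherwise the cause was not tested. DESeq2 gave no adjusted p for 347 genes in LSK and 658 in GMP.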

Other observations

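None of the values here rest on tests chosen after the result was seen, apart from the fits without both WT replicate 1 libraries.

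Most genes of glycolysis, histones and ribosomal proteins did not pass the test in T2F3 LSK. Pgam1, an enzyme of glycolysis, rose 2.59-fold, from 51.2 ± 3.84 to 133 ± 28.5 CPM (SD, n = 3 per group, adjusted p = 0.00361). Hk1, a hexokinase, was 2.26-fold lower (adjusted p = 0.0214), a call lost at adjusted p = 0.0774 without WT LSK replicate 1 and 0.0985 and 0.0717 without T2F3 LSK replicate 1 or 2. Slc2a3, a glucose transporter, was 2.34-fold lower (adjusted p = 0.0388), a call lost at adjusted p = 0.0749, 0.116 and 0.0687 without WT LSK replicate 1, 2 or 3, 0.126 and 0.102 without T2F3 LSK replicate 1 or 2, 0.0579 without WT GMP replicate 2, 0.0631 and 0.0526 without T2F3 GMP replicate 2 or 3 and 0.0535 without both WT replicate 1 libraries. Of 24 glycolysis genes 1 rose and 2 fell (5 and 2 when adjusted over the list alone, median log2 change 0.24, adjusted p = 0.538 with an estimated correlation). Rising glycolysis genes numbered 2 without both WT replicate 1 libraries and 0 by edgeR (3 at an unadjusted p under 0.05) with the library code as a block. Falling glycolysis genes numbered 0 by edgeR (2 at an unadjusted p under 0.05), 1 and 1 without WT LSK replicate 1, 2 or 3, 0 by edgeR (2 at an unadjusted p under 0.05) without T2F3 LSK replicate 1 or 2, 1 without WT GMP replicate 2 and 1 without T2F3 GMP replicate 2 or 3. As a block, the library code gave 0 by edgeR (2 at an unadjusted p under 0.05), against 1 without both WT replicate 1 libraries. Hist1h1a, a linker histone with near-identical relatives, rose 5.82-fold, from 147 ± 26.8 to 853 ± 186 CPM (adjusted p = 0.00417). The histone list had 3 of 68 rising (3 when adjusted over the list alone, median 0.22, adjusted p = 0.858 with an estimated correlation). Rising histone genes numbered 1 without WT LSK replicate 1 or 2 and 5 without WT GMP replicate 3. The number was 2 without both WT replicate 1 libraries and 0 by edgeR (6 at an unadjusted p under 0.05) with the library code as a block. Rpl14, a ribosomal protein gene whose reads pseudogenes can share, rose 3.63-fold (from 23.9 ± 6.34 to 86.8 ± 28.3 CPM, adjusted p = 0.0108). Ribosomal protein genes had 4 of 84 rising (4 when adjusted over the list alone, median 0.43, adjusted p = 0.491 with an estimated correlation), and the risers numbered 1 without WT LSK replicate 1 or 2, 1 and 2 without T2F3 LSK replicate 1 or 3, 2 without WT GMP replicate 2 and 2 without T2F3 GMP replicate 1 or 2. They numbered 1 without both WT replicate 1 libraries and 0 by edgeR (6 at an unadjusted p under 0.05) with the library code as a block. G2 and M phase genes had a median of 0.51 (adjusted p = 0.117 with an estimated correlation), S phase genes of 0.235 (adjusted p = 0.211 with an estimated correlation) and unfolded protein response genes of 0.68 (adjusted p = 0.197 with an estimated correlation). Cholesterol synthesis genes had a median of 0.54 (adjusted p = 0.157 with an estimated correlation) and mitochondrially encoded genes of -0.088 (adjusted p = 0.622 with an estimated correlation).

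Genes of mature cells, stroma and signalling showed mixed changes in T2F3 LSK. Itgam, the CD11b chain of mature myeloid cells, was 4.545-fold lower (from 24.97 ± 7.73 to 5.47 ± 2.36 CPM, SD, n = 3 per group, adjusted p = 0.0086). Mgst1, a glutathione transferase, rose 6.69-fold (adjusted p = 0.00594). The list of maturing neutrophils had 2 of 26 falling and 1 rising (3 and 1 when adjusted over the list alone, median log2 change -0.915, adjusted p = 0.858 with an estimated correlation). Falling neutrophil genes numbered 1 without WT LSK replicate 2 and 1 without T2F3 LSK replicate 1, 2 or 3. There were 6 without both WT replicate 1 libraries and 0 by edgeR (5 at an unadjusted p under 0.05) with the library code as a block. Klrk1, an activating receptor of NK cells, was at least 39.3-fold higher (adjusted p = 0.0139), the 1 of 20 T and NK cell genes that changed (1 when adjusted over the list alone, median -1.31, adjusted p = 0.491 with an estimated correlation). Sparc, a matrix protein of stroma, was at 11.65 ± 10.2 CPM in T2F3 and near 0 in WT (a ratio of 604 with a 95% counting interval of 108 to 23880, adjusted p = 0.0086). Eng, endoglin of endothelium and stem cells, was 2.397-fold lower (adjusted p = 0.0122), a call lost at adjusted p = 0.0566 without T2F3 LSK replicate 1. Of 18 stroma and endothelium genes 4 fell and 2 rose (6 and 3 when adjusted over the list alone). Falling stroma genes numbered 2 without WT LSK replicate 2 and 0 by edgeR (6 at an unadjusted p under 0.05) without T2F3 LSK replicate 1. With the library code as a block there were 0 by edgeR (5 at an unadjusted p under 0.05), and without both WT replicate 1 libraries 5. Rising stroma genes numbered 1 without WT LSK replicate 1, 2 or 3, 1 without T2F3 LSK replicate 1, 2 or 3 and 1 without T2F3 GMP replicate 1, 2 or 3. The library code as a block gave 0 by edgeR (2 at an unadjusted p under 0.05), and leaving out both WT replicate 1 libraries gave 2. That list had a median of -0.97 (adjusted p = 0.157 with an estimated correlation). Nfkbiz, a regulator of NF-kB, was 4.55-fold lower (from 52.4 ± 20.6 to 11.5 ± 2.69 CPM, adjusted p = 0.00821). BCL2A1A, an antiapoptotic gene with near-identical relatives, was at least 17.9-fold higher (adjusted p = 0.0389), a call lost at adjusted p = 0.0941, 0.0995 and 0.0773 without WT LSK replicate 1, 2 or 3, 0.108 and 0.0878 without T2F3 LSK replicate 1 or 2, 0.058 without T2F3 GMP replicate 1 and 0.0684 without both WT replicate 1 libraries. Of 28 genes of NF-kB and inflammatory cytokines 2 rose, 3 fell and 23 did not pass (6 and 4 when adjusted over the list alone, median 0.063, adjusted p = 0.943 with an estimated correlation). Rising genes of this list numbered 0 by edgeR (7 at an unadjusted p under 0.05), 0 by edgeR (8 at an unadjusted p under 0.05) and 0 by edgeR (6 at an unadjusted p under 0.05) without WT LSK replicate 1, 2 or 3, 0 by edgeR (7 at an unadjusted p under 0.05) without T2F3 LSK replicate 1 or 2, 1 without WT GMP replicate 2 or 3 and 0 by edgeR (7 at an unadjusted p under 0.05), 1 and 1 without T2F3 GMP replicate 1, 2 or 3. As a block, the library code gave 0 by edgeR (4 at an unadjusted p under 0.05), against 1 without both WT replicate 1 libraries. Falling genes of it numbered 1 without WT LSK replicate 2 or 3 and 1 without T2F3 LSK replicate 1. The number was 3 without both WT replicate 1 libraries and 0 by edgeR (3 at an unadjusted p under 0.05) with the library code as a block. Medians were -1.42 for MAPK feedback genes (adjusted p = 0.157 with an estimated correlation), 0.64 for the type I interferon response (adjusted p = 0.622 with an estimated correlation) and -0.13 for cytokine receptors (adjusted p = 0.211 with an estimated correlation). DNA methylation genes had a median of 0.021 (adjusted p = 0.858 with an estimated correlation) and p53 targets of 0.15 (adjusted p = 0.933 with an estimated correlation).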
